A study of Mus musculus with 2 samples.

How the data were processed

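Dorsal skin of C57BL/6 mice was measured with Xenium In Situ (version 1 chemistry and a mouse tissue atlas panel) at day 7 after mock treatment or SspA+HDM, in 5-µm sections of formalin-fixed, paraffin-embedded tissue, per the labels. There was 1 sample per treatment. For each sample the authors deposited a table of decoded transcripts, with the gene, position, cell and overlap with a nucleus of each transcript and a quality score (qv, per the file headers), and a table of cell outlines. The score ran from 5.32 to 40 in mock and from 5.28 to 40 in SspA+HDM, on what looked like a Phred scale, so the deposited transcripts had not been filtered at 20. Positions were taken as µm, which the size of the outlines fits. The decoding and segmentation software, its version and its settings are not given in the sources used here, and assignments of transcripts to cells were used as deposited.

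Gene transcripts with a quality score of at least 20 were counted per cell outline. They were 79.4% of the gene transcripts in mock and 78.1% in SspA+HDM. Control probes, control codewords and unassigned codewords were left out. At that quality the 20 control probes held 0.00593% as many transcripts as the genes in mock and 0.00468% in SspA+HDM, and the highest control feature had 34 and 127. Of the 379 gene names, 378 matched a RefSeq symbol and 1 a synonym. Cells linked within 100 µm formed pieces, and pieces with at least 5% of the cells were called strips. Each section held 2, with 19 and 13 cells outside them. Strips are parts of a section, not replicates.

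For the whole section, transcripts in cells were summed per gene and divided by the section total, as CPM over the panel. The 5 most abundant genes took 22.4% of that total in mock and 19.1% in SspA+HDM. A panel total moves with the tissue in the section, so a ratio of CPM is relative to the rest of the panel. Ratios are SspA+HDM over mock, for genes with at least 100 transcripts in at least 1 section. No test was run. Sums have exact Poisson intervals and ratios exact conditional binomial intervals at 95%, which cover counting error only. A count of 0 was set to 3 counts over the section or class, which makes the fold a bound. For each gene list with at least 4 measured members, the median log2 ratio was ranked among 10000 random lists of the same size, matched in 5 bins of mean level. Lists above the 97.5th or below the 2.5th percentile were counted as standing apart, which describes these 2 sections only.

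Cells with at least 20 transcripts were clustered together without integration: log1p of counts scaled to the median total, all panel genes, 30 principal components, 15 nearest neighbours, and Leiden at resolution 1 on a graph weighted by shared neighbours. No doublet caller was run; an outline can take in transcripts of its neighbours, which the spill-over rule addresses only in part. Clusters were named "X-like" from marker lists fixed before the data were examined, as were the gene lists, thresholds and rule for named genes. The scoring rule was set after the panel was known. A marker counted as detected where its CPM plus 50 was at least 2 times the median over clusters plus 50, and a name needed 3 detected markers. The name also needed more markers than any other class among the 10 genes of highest fold with at least 1000 CPM. A tie, or fewer than 100 cells, left a cluster unnamed. The basal and suprabasal keratinocyte lists were joined, since only 1 basal marker was on the panel. Dendritic cells, mast cells, sebaceous gland, melanocytes and B cells had fewer than 3 panel markers and could not be named.

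Shares of cells have exact Clopper-Pearson intervals and were compared by a 1.5-fold size, for classes with at least 50 cells in a section. Within-class CPM were compared for classes with at least 50 cells in both sections, which leaves out the cycling-cell-like class, and for genes with at least 100 transcripts of the class in a section. The spill-over rule left out a pair whose level was under 0.25 of the gene's highest class, in the section where the class had more of it. The stricter rule used 0.5. Distances are between outline centroids, and the cells to which keratinocyte depth was measured leave out unnamed clusters. The measures of strip geometry were added after the files had been seen. Strip length followed the median position in 200-µm bins. Tissue depth ran from the 2nd to the 98th percentile of cells across the strip in 100-µm bins with at least 20 cells. The outer epithelial layer ran from the 2nd percentile of epithelial cells to the 5th percentile of other cells, in 50-µm bins with at least 5 of each. Both were corrected for the slope of the strip. Epithelial cells were those of keratinocyte-like and hair-follicle-like clusters and of clusters with at least 8% of transcripts from Trim29, Dsc3, Serpinb5 and S100a14.

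The named genes are the 12 highest and 12 lowest whole-section ratios, the 2 highest and 2 lowest measured members of each list, and the 3 highest and 3 lowest pairs of each class with at least 200 cells in both sections. Other genes are said to be named after their values were seen. The result of 1 gene list is not reported here. The ratio, list and distance steps were tested on simulated data. For whole-section genes, the mock profile was drawn against the same profile with 30 genes per direction changed 3-fold, over 331 genes in 20 simulations. The size rule of 2-fold found 100.0% of the higher and 99.7% of the lower genes, 0.333% of genes changed 1.5-fold and 0.0242% of unchanged genes. There the most abundant genes were left unchanged and only counting noise was drawn. Shifts of dominant genes or of tissue composition were thus not simulated. A list shifted 4-fold stood apart in 20 of 20 simulations, and known distances were recovered. Alternatives covered scaling, quality score, assignment to cells, low counts, tissue composition, clustering, depth, denominators, spill-over and leaving out each strip. Scaling per mm of strip length and leaving out follicle-led clusters were chosen after seeing the data. The follicle-led clusters were the hair-follicle-like and cycling-cell-like classes, the unnamed epithelial clusters and unnamed cluster 17. The setting with each class at the same weight used named classes with at least 50 cells in both sections. It leaves out the unnamed clusters and the cycling-cell-like class. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used.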

Results

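The series measured RNA in place in mouse back skin with the Xenium In Situ platform, which decodes single transcripts of a chosen gene panel by their position in a tissue section. Mice were C57BL/6, their back skin had been shaved and depilated, and 2 treatments were compared: PBS put on the skin (mock), and SspA together with HDM put on the skin (SspA+HDM). Skin was taken at day 7. There was 1 sample per treatment, so no difference has a replicate check, no test was run, and every interval covers counting error only. The panel held 379 genes. The mock section gave 2461475 gene transcripts of quality 20 or above and the SspA+HDM section gave 8124205, of which 94.5% and 97.6% lay inside a segmented cell outline. The mock section held 15932 segmented cells with a median of 103 transcripts, and the SspA+HDM section held 46142 with a median of 121. Each section was made of 2 separate strips of skin, with 7502 and 8411 cells in mock and 21469 and 24660 in SspA+HDM. The labels do not say whether the strips came from separate animals, and the strips of a section may be neighbouring sections of 1 specimen, whose agreement would repeat nearly the same tissue. They are given side by side and were not used as replicates.

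The first question was what tissue the sections held, and the SspA+HDM strips were deeper and held more cells per length. Mock strips held 1087 and 1198 cells per mm of length, against 2800 and 3204 in the SspA+HDM strips. The median depth of the tissue, from the outermost to the deepest cells, was 214 and 219 µm in mock and 354 and 358 µm in SspA+HDM. The outer epithelial layer, measured from the surface to the outermost non-epithelial cells, had a median of 40.3 and 39.6 µm in the mock strips and 82.4 and 85.7 µm in the SspA+HDM strips. In 1 of 265 mock positions and 4 of 299 SspA+HDM positions this value was at or below 0. These measures were added after the files had been seen.

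**Figure D1:**
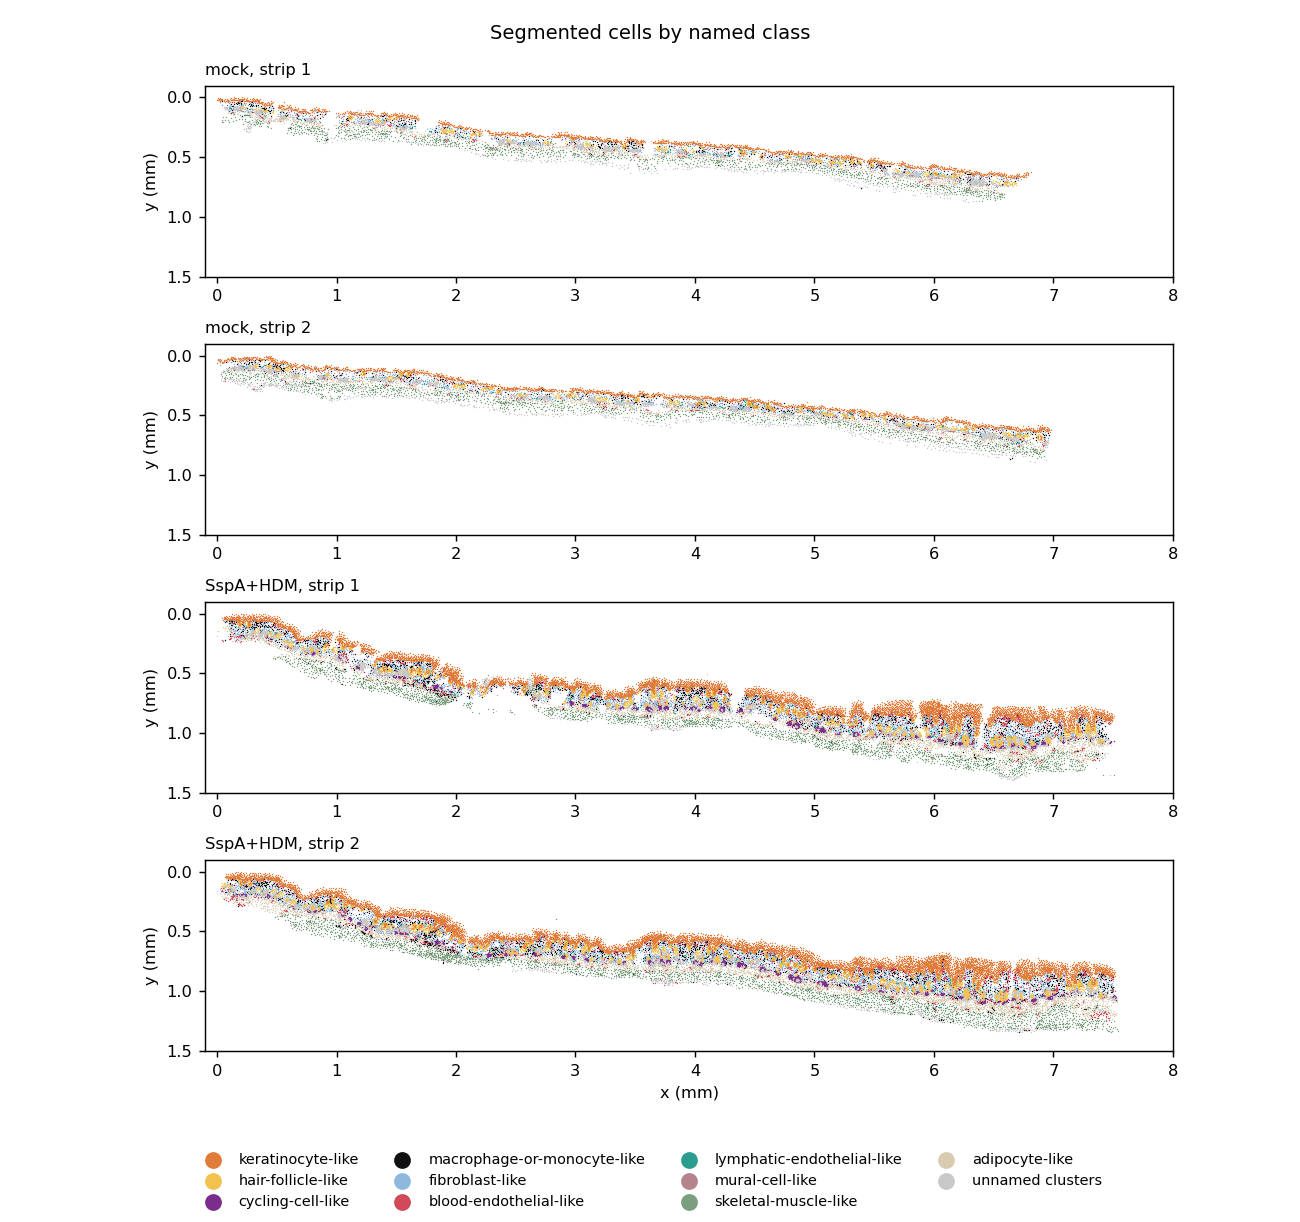
Positions of segmented cells in the 4 strips, in mm, with the skin surface at the top of each panel and cells coloured by named class. The keratinocyte-like band at the surface is deeper in both SspA+HDM strips, and cycling-cell-like cells (2061 in SspA+HDM, 11 in mock) lie deep in both of those strips.

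**Figure D2:**
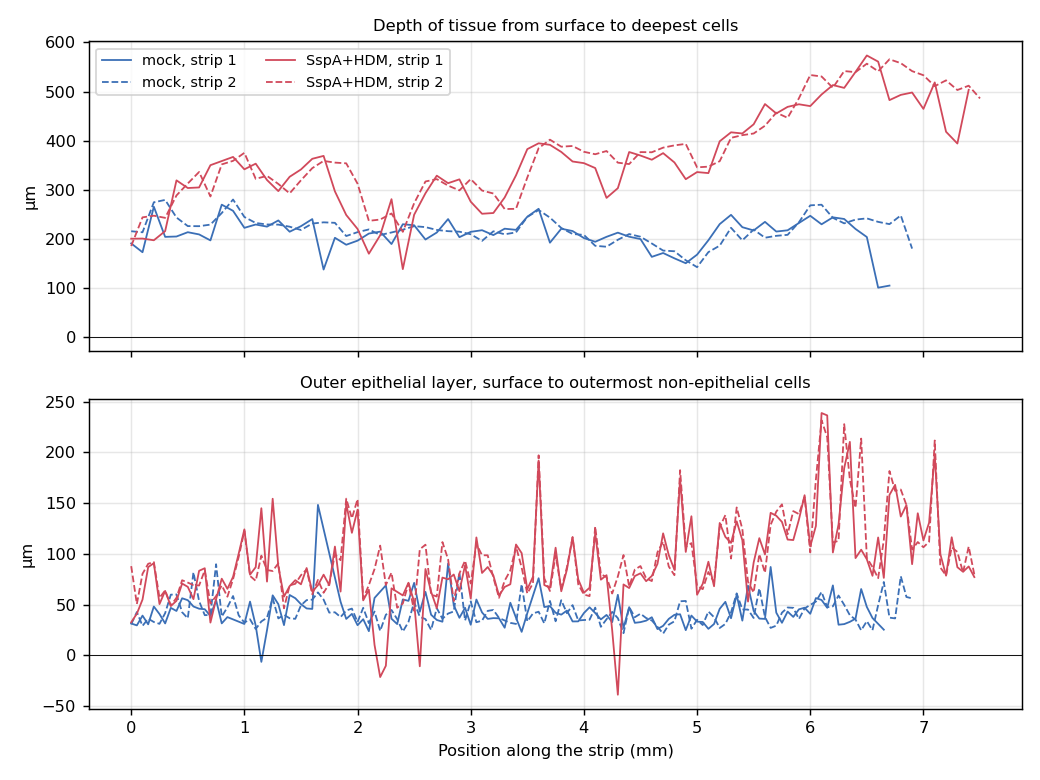
Depth of the tissue (upper panel) and of the outer epithelial layer (lower panel), both in µm, along the length of each strip in mm. Mock strips have medians of 214 and 219 µm for the tissue, against 354 and 358 µm in SspA+HDM, and both SspA+HDM strips are deepest toward the right end.

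Over the whole section, the 12 genes with the highest SspA+HDM to mock ratios included a stress keratin, protease inhibitors and a cornified envelope gene. The stress keratin gene Krt16 stood at 1647 CPM over the panel in mock and 34029 in SspA+HDM, a ratio of 20.7 (interval 20.02 to 21.3). Cstdc4 and Stfa2l1, which belong to the cystatin family of cysteine protease inhibitors, were 89.9-fold (80.8 to 100.2) and 221-fold (182 to 272) higher. Uox, the gene of urate oxidase, had the highest ratio of the panel, 342 (232 to 529), from 25 transcripts in mock and 29195 in SspA+HDM. The secreted peptide gene 2610528A11Rik was 48.0-fold higher (37.0 to 63.4). Cnfn, which encodes the cornified envelope protein cornifelin, was 10.97-fold higher (10.3 to 11.7). The retinol-binding protein gene Rbp2 was 15.9-fold higher (15.1 to 16.8), and Hsd11b2, whose enzyme inactivates glucocorticoids, was 14.7-fold higher (9.93 to 22.8). The phosphate carrier gene Slc34a2, the glucose carrier gene Slc5a1 and Fxyd4, a regulator of the sodium pump, were 11.2-fold (10.5 to 12.1), 10.8-fold (10.01 to 11.6) and 10.3-fold (8.56 to 12.6) higher. Cxcr2, a chemokine receptor best known from neutrophils, was at 67.9 CPM in mock and 904 in SspA+HDM, 13.3-fold higher (11.4 to 15.7). Without a quality filter the log2 ratios of Uox and Hsd11b2 were 6.97 and 2.43, against 8.42 and 3.88, and that of Hsd11b2 was 1.36 without follicle-led clusters. Over the nucleus those of Uox, Stfa2l1, Cstdc4 and Fxyd4 were 7.54, 6.39, 5.41 and 2.65, against 8.42, 7.79, 6.49 and 3.37. In mock Uox and Hsd11b2 had 25 transcripts each, fewer than the highest control feature of that section (34), so the mock level behind these ratios lay within the range of the controls.

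The lowest ratios belonged to a different set of genes. Retnla, which encodes the secreted factor RELM alpha and is linked to type 2 macrophage activation, was at 5367 CPM in mock and 548 in SspA+HDM, 9.80-fold lower (9.46 to 10.1). Of its 12480 mock transcripts, 438 lay in macrophage-or-monocyte-like cells. The epithelial genes Gabrp, Kcnj16 and B4galnt2 were 8.24-fold (6.86 to 9.93), 7.69-fold (6.56 to 9.04) and 7.22-fold (5.38 to 9.78) lower. Lce1m, a late cornified envelope gene, was 7.09-fold lower (6.79 to 7.41), opposite to Cnfn. Marco, a scavenger receptor of macrophages, was 4.55-fold lower (3.67 to 5.66), and Ifitm6 was 4.38-fold lower (3.97 to 4.84). The connective tissue genes Pi16, Igfbp6 and Pcolce2 were 3.85-fold (3.78 to 3.91), 3.40-fold (3.31 to 3.48) and 3.07-fold (2.995 to 3.15) lower. Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, was 3.05-fold lower (2.87 to 3.25), and the smooth muscle gene Cnn1 3.03-fold lower (2.82 to 3.26). Per mm of strip length, where the SspA+HDM skin held more cells of most classes, the last 3 of these genes (Pcolce2, Lyve1 and Cnn1) had ratios of 1.01, 1.01 and 1.02. Retnla, Gabrp, Kcnj16, B4galnt2 and Lce1m kept ratios of 0.315, 0.375, 0.402, 0.428 and 0.436 on that scale, while Marco, Ifitm6, Pi16 and Igfbp6 were at 0.679, 0.705, 0.803 and 0.910, less than 2-fold lower. Without a quality filter the log2 ratios of B4galnt2, Gabrp and Marco were -1.63, -2.27 and -1.25, against -2.85, -3.04 and -2.19. B4galnt2 had 68 transcripts in SspA+HDM, fewer than the highest control feature there (127). With each class at the same weight in both sections those of Lyve1 and Cnn1 were -0.80 and -0.83, less than 2-fold lower, and those of Igfbp6, Pi16 and Retnla were -1.02, -1.30 and -2.44, against -1.76, -1.94 and -3.29. That setting also leaves out unnamed cluster 21, with 736 mock and 249 SspA+HDM cells. Retnla, Igfbp6, Pi16 and Lyve1 were among its leading genes, so their smaller sizes may not come from equal weights alone. Without the muscle, adipocyte and mural classes Igfbp6, Pi16, Ifitm6, Marco and Retnla were at -2.91, -3.11, -3.50, -2.88 and -4.45.

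**Figure D3:**
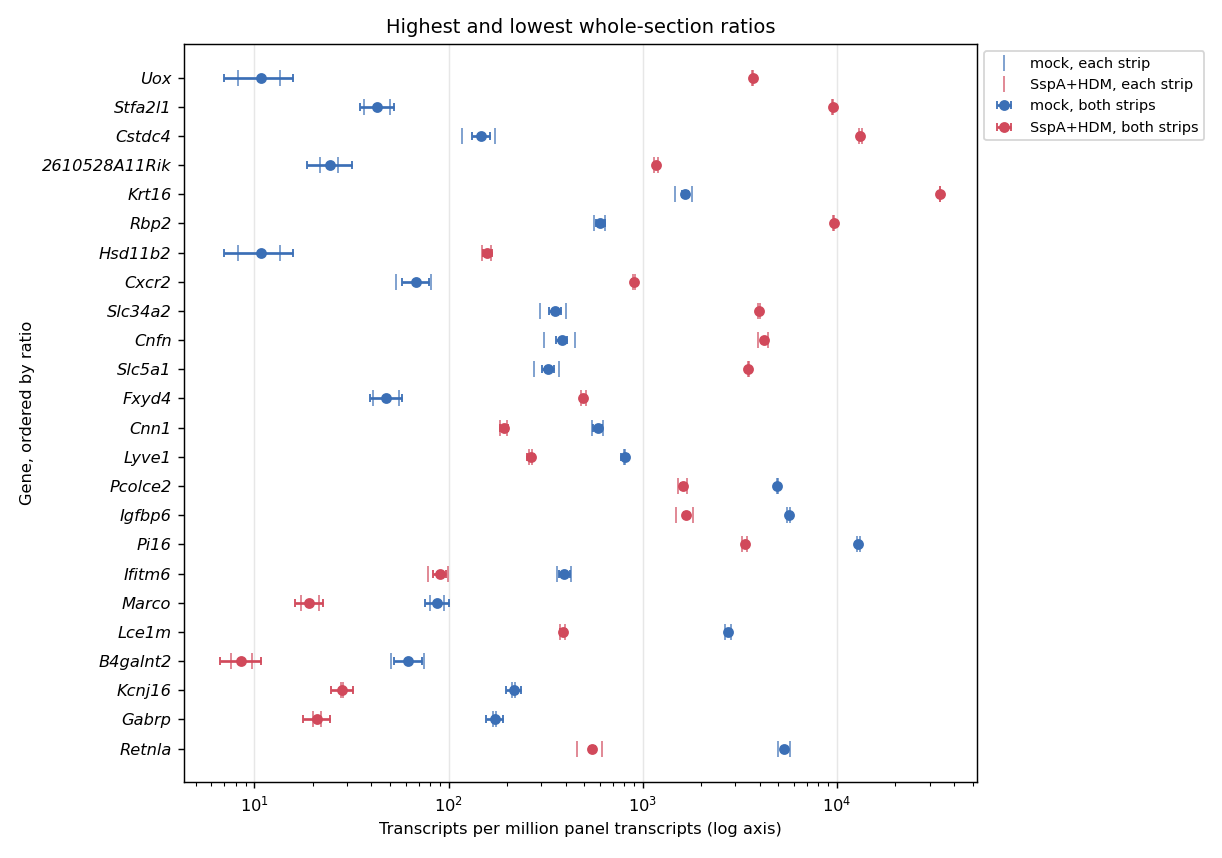
CPM over the panel (log axis) of the 12 genes with the highest and the 12 with the lowest ratio, for mock and SspA+HDM. Points are whole sections with exact Poisson intervals and short lines are the strips, and for every gene shown both strips of one treatment lie on the same side of both strips of the other.

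Counted by size alone, 51 of 346 genes with at least 100 transcripts in a section were at least 2-fold higher in SspA+HDM and 44 were at least 2-fold lower. For 44 and 32 of the 346 genes the same held between every mock strip and every SspA+HDM strip. The count of lower genes depended on how tissue composition was handled, at 75 without the muscle, adipocyte and mural classes and 28 with each class at the same weight in both sections. It also depended on the scaling, which shifts every gene alike, with 71 higher and 23 lower genes per segmented cell and 268 higher and 5 lower per mm of strip length.

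Among the gene lists fixed before the data were examined, 7 had at least 4 measured members, and 2 stood apart from 10000 random lists matched on expression. In the neutrophil and IL-17 list, 3 of 5 measured members were at least 2-fold higher and 2 at least 2-fold lower. Its median log2 ratio of 1.40 lay at the 99.5th percentile of the random lists. From transcripts over the nucleus alone the median was 0.75 at the 96.96th percentile, inside the random range, and per mm of strip length all 5 members were higher. Cxcr2 was 13.3-fold higher and Csf3r, the receptor gene for granulocyte colony-stimulating factor, 3.34-fold higher (143 against 479 CPM), and Mmp8, a neutrophil collagenase gene named after its value was seen, was 2.65-fold higher. The list median was the value of Mmp8, which had 44 transcripts in mock. Of the 7171 Cxcr2 transcripts in SspA+HDM, 5066 lay in keratinocyte-like clusters 5 and 16 (below), so the list does not measure neutrophils alone. Mmp9 and the decoy receptor gene Il1r2 were 2.59-fold and 2.17-fold lower. The skeletal muscle list lay at the 0.69th percentile with a median log2 ratio of -1.04, and 3 of its 4 members were at least 2-fold lower. Pvalb was 2.42-fold lower and Ttn 2.09-fold lower, with Actn3 at 2.03-fold and Des at 1.47-fold lower. With each class at the same weight in both sections the list lay inside the random range, at the 12.96th percentile with a median of -0.45 and 0 members 2-fold lower. Per mm of strip length all 4 members were higher, with a median of 0.59, against 1.67 over all genes. That scaling shifts every gene alike, so the rank (0.62th percentile) could move only through the matching of the random lists. Skeletal-muscle-like cells were 14.8% of mock and 9.59% of SspA+HDM cells.

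The other 5 lists of that size lay inside the random range. All 5 members of the epidermal differentiation and barrier list were higher, with a median log2 ratio of 0.40 at the 81.6th percentile. Without the muscle, adipocyte and mural classes 3 of the 5 were higher (median 0.02), with each class at the same weight 4 (median 0.04), and without follicle-led clusters all 5 (median 0.92). Aqp3, the water and glycerol channel of basal keratinocytes, was 4.37-fold higher and the cornified envelope gene Ivl 1.95-fold, while Lor and Sbsn were 1.28-fold and 1.26-fold higher. The adipocyte list had a median of -0.90 at the 4.40th percentile, with Retn 2.09-fold and Car3 1.95-fold lower, Cd36 1.78-fold lower and Pck1 1.09-fold higher. Without SspA+HDM strip 2 it lay at the 2.29th percentile with a median of -1.01, below the random range. The matrix list had a median of -0.10 at the 38.5th percentile, from Bgn at 1.89-fold and Lum at 1.02-fold higher to Col8a1 at 1.17-fold and Timp3 at 1.71-fold lower. In the endothelial list (median -0.16, 41.5th percentile), Vwf and Plvap were 2.04-fold and 1.46-fold higher, and the lymphatic genes Prox1 and Lyve1 were 1.81-fold and 3.05-fold lower. In the myeloid list (median 0.03, 54.7th percentile), the chemokine gene Ccl12 was 2.76-fold higher and the complement receptor gene C5ar1 1.23-fold higher, against 1.41-fold lower for Ccl9 and 1.61-fold lower for C3. The small medians turned with composition: the matrix median was 0.13 with each class at the same weight, and the endothelial and myeloid medians were 0.11 and -0.33 without the muscle, adipocyte and mural classes. Per mm of strip length all members of these 5 lists were higher, on a scale where the median log2 ratio of all genes was 1.67.

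Lists with 1 to 3 measured genes were described by their values only. For cell division, Stmn1 was 2.52-fold, Ube2c 2.19-fold and Cenpf 2.17-fold higher. The 2-fold size was lost for all 3 without follicle-led clusters (log2 ratios from -0.06 to 0.58, 1 of them lower), with each class at the same weight (0.03 to 0.61) and without the muscle, adipocyte and mural classes (0.72 to 0.97). The first 2 of these settings leave out the cycling-cell-like class (below), which was named from these 3 genes. A loss of size there was partly built in. In the keratinocyte activation list, Krt16 was 20.7-fold and Areg, which encodes a ligand of the EGF receptor, 4.28-fold higher, and Mmp9 was 2.59-fold lower. The 2 measured genes of the type 2 list went opposite ways, with Areg higher and Retnla 9.80-fold lower. Among T cell genes, Cd8a was 4.14-fold higher (29.7 against 123 CPM) and Cd3d 1.66-fold higher, while Ctla4 was 1.11-fold lower. Without a quality filter the highest log2 ratio of these 3 genes was 1.34, against 2.05. For the hair follicle, Lhx2 was 2.14-fold higher, and Krt79 and Sox9 were 1.09-fold and 1.06-fold higher. Without follicle-led clusters the highest log2 ratio of the 3 was 0.90, less than 2-fold, and without the muscle, adipocyte and mural classes it was 0.71 and 2 of the 3 were lower. The first of these settings leaves out the hair-follicle-like class, which was named from these 3 genes. Single genes stood for the interferon list (Rsad2, 1.34-fold higher) and the antigen presentation list (Psmb8, 1.03-fold lower). The platelet genes Ppbp and Pf4 were 1.09-fold and 1.2004-fold lower.

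The cell make-up was compared next, by clustering 15306 mock and 44282 SspA+HDM cells together into 24 clusters, of which 18 could be named from fixed markers into 10 classes. Macrophage-or-monocyte-like cells, the only leukocyte class that a cluster could be named for, made up 4.31% of mock cells (exact binomial interval 3.996 to 4.65) and 6.84% of SspA+HDM cells (6.605 to 7.08), a ratio of 1.59. The ratio of this class was 0.9999 with the sections clustered separately, and 1.17 both after thinning the SspA+HDM cells to the mock depth and among cells with at least 40 transcripts. After thinning, a T-cell-like class was also named, and with it the leukocyte ratio was 1.66. Per mm of strip there were 47.4 in mock and 197 in SspA+HDM. Its leading genes were Ms4a6c, Ms4a7, Mpeg1 and Clec4a3, and Csf3r, a gene known from granulocytes, was among them. In mock this class held Csf3r at 2117 CPM and 0 Cxcr2 transcripts, so Csf3r alone does not show that it held granulocytes. The class may still not be purely of macrophages. Blood-endothelial-like cells, whose leading genes also included the mural genes Rgs5 and Myh11, were 2.59% (2.35 to 2.86) and 5.17% (4.96 to 5.38), with 28.5 per mm of strip in mock and 149 per mm in SspA+HDM. Cycling-cell-like cells, led by the follicle gene Lhx2, Atp6v1b1 and Tbx1, with the division genes Cenpf and Ube2c further down the 10 leading genes, were 0.0719% (0.0359 to 0.129) and 4.65% (4.46 to 4.85). That class was a single cluster with 11 of its 2072 cells from mock, so it cannot be separated from the library itself. Among cells with at least 40 transcripts no cluster took that name. The whole mock section held 1453 Cenpf and 1068 Ube2c transcripts, so the share of this class does not measure how many cells were dividing.

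The shares of 3 classes were at least 1.5-fold lower in SspA+HDM. Lymphatic-endothelial-like cells were 1.999% (1.78 to 2.23) and 0.908% (0.822 to 1.001), mural-cell-like cells 3.27% (2.99 to 3.56) and 1.39% (1.28 to 1.505), and skeletal-muscle-like cells 14.8% (14.3 to 15.4) and 9.59% (9.32 to 9.87). Per mm of strip these classes were not fewer. Lymphatic-endothelial-like cells were at 22.0 and 26.2 per mm, mural-cell-like cells at 35.9 and 40.1, and skeletal-muscle-like cells at 163 and 276, in mock and SspA+HDM. The 4 other classes had share ratios between 0.853 and 1.37: adipocyte-like (9.79% and 8.35%), fibroblast-like (8.87% and 9.68%), keratinocyte-like (23.1% and 30.003%) and hair-follicle-like (9.75% and 13.4%). These ratios turned with the clustering: that of keratinocyte-like cells was 0.753 and that of fibroblast-like cells 0.712 at Leiden resolution 2, and that of hair-follicle-like cells 0.673 at resolution 0.5 and 0.513 with the sections clustered separately. At resolution 2 clusters 7, 16 and 17, with keratinocyte genes such as Cstdc4 and Calm5 leading, were left unnamed, with 2133, 1437 and 1390 SspA+HDM cells against 17, 4 and 35 in mock. Fibroblast-like cells took in cluster 25 there, led by Retnla, C3, Igfbp6 and Pi16, with 744 mock and 263 SspA+HDM cells. At resolution 1 a cluster with nearly the same leading genes was left unnamed, with 736 and 249 cells. The fibroblast-like shares of 8.87% and 9.68% leave it out. Per mm, keratinocyte-like cells were at 253 and 865 and fibroblast-like cells at 97.47 and 279. Clusters left unnamed made up 21.4% of mock and 10.04% of SspA+HDM cells. Their epithelial part was 12.6% and 3.92%, so the keratinocyte-like and hair-follicle-like shares leave out more of the mock epithelium. Most of that part in mock was cluster 15, led by Krt13, Lhx2 and Tbx1, at 8.59% of mock and 1.12% of SspA+HDM cells.

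**Figure D4:**
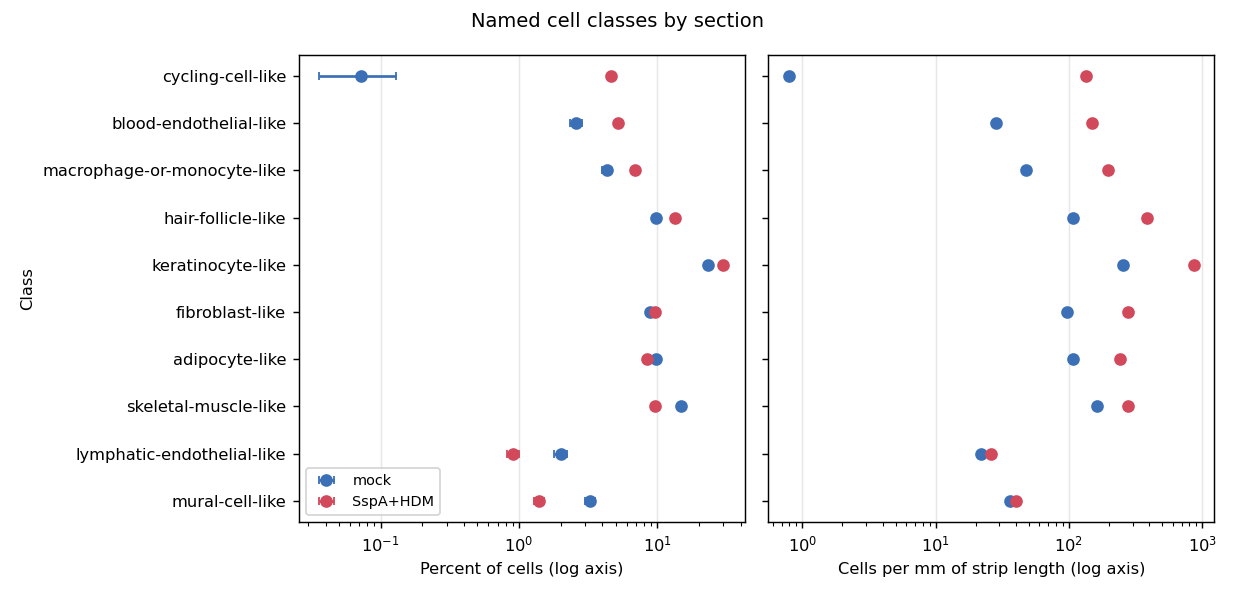
Share of cells in percent with exact binomial intervals (left) and cells per mm of strip length (right), both on log axes, for the 10 named classes in mock and SspA+HDM. Lymphatic-endothelial-like cells are lower as a share (1.999% and 0.908%) and close per mm (22.0 and 26.2).

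Within keratinocyte-like cells, 22 of 84 genes kept by the spill-over rule were at least 2-fold higher in SspA+HDM and 30 at least 2-fold lower. Different clusters held most of the class in each section. In mock, cluster 7 held 3180 of the 3529 keratinocyte-like cells, and in SspA+HDM clusters 2, 5, 10, 16 and 19 held all but 45 of 13286. Uox had 4 transcripts in mock keratinocyte-like cells and 28816 in SspA+HDM, 6.26 and 7745 CPM within the class. Stfa2l1 was 310-fold (229 to 432) and Serpinb11, a serpin gene, 69.2-fold higher, with 34 and 13713 transcripts. Uox and Stfa2l1 were also among the leading genes of clusters 5, 16 and 19, and Serpinb11 of cluster 19, so their ratios are not independent of the clustering. Ifitm6, Kcnj16 and B4galnt2 were 55.3-fold (43.7 to 71.1), 36.5-fold (28.4 to 47.4) and 35.8-fold (22.7 to 58.9) lower. In hair-follicle-like cells the secreted Wnt inhibitor gene Sfrp1 was 33.1-fold higher (28.3 to 39.1), 2610528A11Rik 65.1-fold (22.2 to 316) and Hsd11b2 58.3-fold (16.1 to 483) higher, while Bst1 was 6.98-fold, Cldn4 4.65-fold and Ivl 4.49-fold lower. Sfrp1 and Hsd11b2 were among the leading genes of cluster 11 and 2610528A11Rik of cluster 6. That class was spread over clusters 6 and 13 in mock, and clusters 6 and 11 held most of it in SspA+HDM.

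In the stroma, fibroblast-like cells had lower levels of Il1r2 (6.74-fold), Pi16 (5.99-fold), a marker of adventitial fibroblasts, and Sod3 (5.08-fold), the extracellular superoxide dismutase gene. They had higher levels of Cxcr2 (12.996-fold, from 3 and 138 transcripts), Gng11 (3.86-fold) and Gap43 (3.67-fold). At Leiden resolution 2 these cells split largely by section, with 113 mock and 3647 SspA+HDM cells in cluster 1 and 1124 and 173 in cluster 22, which had Pi16, Il1r2 and Sod3 among its leading genes. Retnla was also lower in each other class where it was kept, by 20.4-fold in blood-endothelial-like, 18.0-fold in lymphatic-endothelial-like, 13.5-fold in adipocyte-like, 5.82-fold in macrophage-or-monocyte-like and 2.73-fold in skeletal-muscle-like cells. An unnamed cluster led by Retnla and Pi16 held 4.81% of mock and 0.562% of SspA+HDM cells, and its transcripts can lie in neighbouring outlines. At Leiden resolution 2 a cluster with nearly the same leading genes was named fibroblast-like, with 744 mock and 263 SspA+HDM cells. Adipocyte-like cells held more Cxcr2 (2 and 280 transcripts, 53.6-fold, interval 14.7 to 445), Csf3r (8.09-fold) and the hemopexin gene Hpx (41.0-fold, 15.9 to 151, from 4 mock transcripts), and less Pcolce2 (2.16-fold) and Mamdc2 (2.05-fold). Fibroblast-like and adipocyte-like Cxcr2, at 431 and 520 CPM in SspA+HDM, would not pass the stricter spill-over rule. The reference of that rule was the keratinocyte-like class, where Cxcr2 was at 1357 to 2103 CPM over the left and right parts of the strips. Macrophage-or-monocyte-like cells held it at 1058. Over the named non-epithelial classes there, cells with Cxcr2 held Csf3r 2.59 times (2.26 to 2.95) and the leukocyte gene Rac2 1.89 times (1.64 to 2.15) as often as predicted. Transcripts of leukocytes in these outlines were not told apart from expression by the cells. In macrophage-or-monocyte-like cells Cxcr2 had 0 transcripts in mock and 229 in SspA+HDM, which is at least 16.99-fold higher against a floor of 3 counts. 2610528A11Rik was at least 9.35-fold and Ccn3 9.27-fold higher there, and Dnase1l3 and Pi16 were 5.26-fold and 5.00-fold lower. However, 2610528A11Rik was a leading gene of keratinocyte-like cluster 2, and Krt16 stood at 374 CPM in mock and 10579 in SspA+HDM in these outlines. Pi16 was at 30412 CPM here in mock, against 61505 in mock fibroblast-like cells. Transcripts of neighbouring cells were not told apart from expression here, nor for Pi16 in other classes that are not fibroblast-like. Blood-endothelial-like cells had Satb1, Runx2 and the urea carrier gene Slc14a1 3.58-fold, 3.43-fold and 3.01-fold higher and Timp4 and Igfbp6 4.74-fold and 3.47-fold lower.

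Mural-cell-like cells had Ms4a6b, Aspn and Tnfaip6 2.87-fold, 2.52-fold and 2.12-fold higher, and Il1r2, Pi16 and Igfbp6 5.08-fold, 4.27-fold and 3.29-fold lower. In lymphatic-endothelial-like cells no gene was 2-fold higher, and Aspn, Psmb8 and Serpina3n were 1.80-fold, 1.68-fold and 1.64-fold higher, with Pi16 and Igfbp6 3.94-fold and 3.79-fold lower. Skeletal-muscle-like cells had the slow and cardiac troponin C gene Tnnc1 29.7-fold higher (19.7 to 47.0), from 23 and 1217 transcripts. Thbs4 and C3 were 2.20-fold and 2.13-fold higher there, and Ppp1r1a and Ldhb 1.43-fold and 1.27-fold lower. Over the 9 classes compared, 112 of 660 gene and class pairs were at least 2-fold higher and 89 at least 2-fold lower. These counts moved to 254 and 193 without the spill-over rule and to 68 and 54 with the stricter one.

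Cxcr2 and Csf3r were placed differently in the SspA+HDM section. Cxcr2 was highest in the keratinocyte-like clusters 5 and 16, at 3073 and 2146 CPM, where Csf3r was at 14.7 and 7.12. In the macrophage-or-monocyte-like cluster Cxcr2 was at 1058 and Csf3r at 5678 CPM, and in the adipocyte-like cluster they were at 520 and 2239. In the main mock keratinocyte-like cluster Cxcr2 was at 184 CPM. Clusters 5 and 16 were singled out after their values had been seen.

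**Figure D5:**
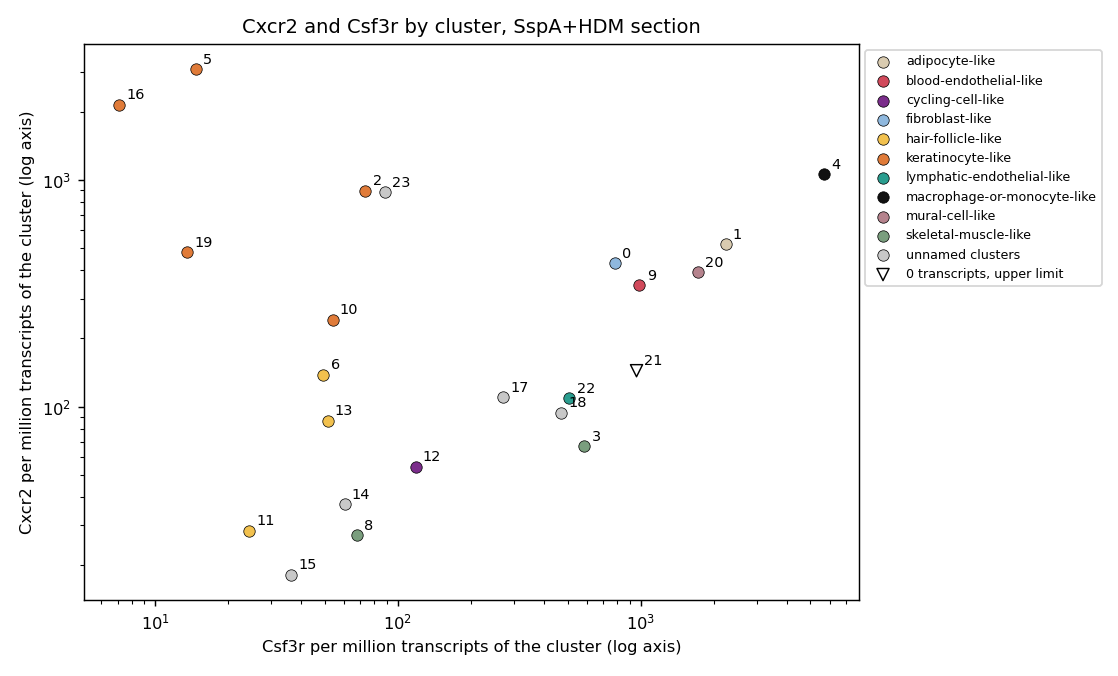
Cxcr2 against Csf3r, both in CPM of a cluster on log axes, for clusters of the SspA+HDM section, with cluster numbers beside the points and colour for the named class. Cluster 21, which had 0 Cxcr2 transcripts, is drawn as an open triangle at the level of 3 counts, 144 CPM, as an upper limit, and keratinocyte-like clusters 5 and 16 (Cxcr2 at 3073 and 2146) lie apart from the leukocyte cluster 4 (Csf3r at 5678).

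Position was compared last. The median distance from a macrophage-or-monocyte-like cell to the nearest keratinocyte-like cell was 28.0 µm in mock (binomial interval of the median 26.3 to 29.8, 660 cells) and 42.4 µm in SspA+HDM (40.8 to 44.3, 3028 cells). The distances were 19.4 and 24.5 µm with follicle cells counted as keratinocytes, and 29.8 and 36.8 µm at Leiden resolution 2, where T-cell-like cells were also counted. For all other non-keratinocyte cells it was 67.2 and 86.7 µm, so these leukocytes lay closer than those cells in both sections. Within 50 µm of a keratinocyte-like cell lay 79.7% (76.4 to 82.7) of these leukocytes in mock and 56.7% (55.0 to 58.5) in SspA+HDM. The depth of keratinocyte-like cells, as the distance to the nearest cell of a named class other than keratinocyte-like or hair-follicle-like, had a median of 20.5 µm in mock (20.1 to 20.8) and 28.1 µm in SspA+HDM (27.7 to 28.5). Its 95th percentile was 38.96 µm and 76.6 µm. The strips of a section differed by less than the sections did, with medians of 20.8 and 20.1 µm in mock and 28.6 and 27.6 µm in SspA+HDM. With follicle cells counted as keratinocytes the median depths were 18.3 and 21.0 µm.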

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

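The spread of Cxcr2 over clusters, the thinning test of the follicle clusters, the comparison of adipocyte-like cells per mm and the Csf3r to Cxcr2 ratio were tests chosen only after the result was seen. The tests of co-detection in keratinocyte-like cells and of windows along the strips were set beforehand.

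Transcripts outside segmented cells entered only an alternative setting, and a higher share of them in SspA+HDM than in mock was taken as a signal outside the main measurement. Among 129 genes with at least 100 such transcripts in SspA+HDM, 1 had a share above mock with intervals that do not overlap. For Calm4, a calmodulin-like gene of differentiated epidermis, 4.96% of transcripts (4.89 to 5.03) lay outside cells in SspA+HDM, against 4.32% (4.16 to 4.48) in mock. The median share over those genes was 1.36% in SspA+HDM and 3.54% in mock.

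The Cxcr2 transcripts in SspA+HDM keratinocyte-like cells were weighed first. Even spread over the tissue was argued against by the 12.7-fold span of Cxcr2 CPM between keratinocyte-like clusters 5 and 10. In clusters 5 and 16 there were 22 Csf3r and 5066 Cxcr2 transcripts, and this Csf3r to Cxcr2 ratio was 0.000809 of the one in the leukocyte cluster, used in place of a pure neutrophil cluster, which argues against neutrophils as the source there. The reference may lie above the ratio of neutrophils, since mock cells of that leukocyte cluster held Csf3r at 2117 CPM and 0 Cxcr2 transcripts. Over all keratinocyte-like cells, those with Cxcr2 held Csf3r 1.46 times as often as their totals predict (0.965 to 2.13), which leaves neutrophils open as a contributor. Expression of Cxcr2 by suprabasal keratinocytes is a candidate explanation, and an off-target probe was not tested.

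The Cd8a transcripts in the same class looked different. Cells with Cd8a held Cd3d 4.81 times as often as their totals predict (3.91 to 5.85), which argues against expression by keratinocytes or a stray probe signal spread over them. They held Rac2, a gene of leukocytes, 3.55 times as often as predicted (2.999 to 4.17), which may mean that T cells within the epidermis were drawn into keratinocyte outlines. At Leiden resolution 2 a T-cell-like cluster had 982 cells in SspA+HDM and 17 in mock, but its leading genes besides Cd3d and Cd8a included Cstdc4, Stfa2l1 and Uox of the SspA+HDM keratinocyte-like cells, so its count is not independent of keratinocyte state. A biological difference between the treatments remains a hypothesis, since each treatment is 1 section.

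Clusters 11, 12 and 17, led by follicle genes such as Lhx2, Wif1 and Acan, lay almost only in SspA+HDM (2165, 2061 and 1493 cells, against 43, 11 and 36 in mock), while unnamed cluster 15, with Lhx2, Tbx1 and Wif1 also among its leading genes, went the other way (495 cells, against 1315 in mock). At least 5 cells of cluster 12 were found in 31 of the 32 windows of 500 µm, or 96.9% (83.8 to 99.9), which argues against a local patch of follicles for that cluster. The interval takes windows as independent, but neighbouring windows are not, and the 2 strips may repeat nearly the same tissue. Clusters 11 and 17 were not tested in this way. After thinning to the mock depth the ratio of cycling-cell-like shares was 106. The median totals were close before thinning (103 and 121 transcripts per segmented cell in mock and SspA+HDM). Thinning thus removed few transcripts and had little room to change a ratio that rests on 11 mock cells, so it was a weak test of deeper counting. A hair cycle stage that differed between the 2 specimens, both depilated, cannot be told apart from an effect of treatment in this design. Adipocyte-like cells were 2.24 times as many per mm, which either could give.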

How the results depend on the processing

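Each value under an alternative setting is from the same 2 sections, and the scaling per mm of strip length and the setting without follicle-led clusters were chosen after seeing the data. Of 17 settings for genes, 2 filters on low counts cannot move a ratio and 4 scalings shift all genes alike. In the other 11 the 24 whole-section genes with the highest or lowest ratios kept their direction in all 260 values. Among the scalings, 3 values turned, all per mm of strip length, where the log2 ratios of Pcolce2, Lyve1 and Cnn1 were 0.00878, 0.0186 and 0.0268. The size of some ratios moved: without a quality filter the log2 ratios of Uox, Hsd11b2, B4galnt2 and Marco were 6.97, 2.43, -1.63 and -1.25, against 8.42, 3.88, -2.85 and -2.19. The median log2 ratio of all genes was 0.05 in the reported setting, 0.28 per segmented cell, -0.20 without muscle, adipocyte and mural classes, -0.16 over the nucleus, -0.10 without follicle-led clusters and 1.67 per mm. The share of higher among called genes was 53.7% in the reported setting, 75.5% per cell, 31.8% without those classes and 98.2% per mm. Genes 2-fold lower numbered 23 per segmented cell, 75 without muscle, adipocyte and mural classes, 28 with each class at the same weight and 5 per mm, and genes 2-fold higher 268 per mm. Of the 51 higher genes, 39 stayed at least 2-fold higher without follicle-led clusters. Of the gene lists, 1 stood apart over the nucleus, where the neutrophil and IL-17 list lay at the 96.96th percentile, and 1 with equal class weights, where the skeletal muscle list lay at the 12.96th. Without SspA+HDM strip 2, 3 lists stood apart, the adipocyte list among them.

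Higher classes numbered 1 with cells of at least 10 or at least 40 transcripts, 6 per square mm of cell area and 8 per mm of strip. At 10 transcripts it was the cycling-cell-like class (ratio 66.2) and at 40 the blood-endothelial-like class (1.61). No cluster was named cycling-cell-like at 40 transcripts. Lower classes numbered 5 at resolution 2, 1 in the denominator without muscle, adipocyte and mural classes, 1 per square mm and 0 per mm. Per mm, the ratios of lymphatic-endothelial-like, mural-cell-like and skeletal-muscle-like cells were 1.19, 1.12 and 1.69, the opposite direction to their shares. The leukocyte share ratio of 1.59 became 1.39 and 1.17 at 10 and 40 transcripts, 2.25 at resolution 2, 1.45 with separate clustering, 1.66 after thinning, 1.42 in the reduced denominator, 2.37 per square mm and 4.16 per mm. With separate clustering the macrophage-or-monocyte-like ratio alone was 0.9999. At resolution 0.5 no leukocyte class could be named, so there was no share or distance.

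Within-class counts of higher and lower pairs were 177 and 138 with a minimum of 20 transcripts, 254 and 193 without the spill-over rule and 68 and 54 with the stricter rule. The SspA+HDM minus mock difference in leukocyte distance, 14.4 µm, was 11.9 and 21.2 µm at 10 and 40 transcripts, 7.06 µm at resolution 2, 5.16 µm with follicle cells as keratinocytes, and 16.2 and 12.1 µm without mock strip 1 or 2. That in keratinocyte depth, 7.62 µm, was 9.23 µm at both 10 and 40 transcripts, 10.7 and 2.99 µm at resolutions 0.5 and 2, 2.67 µm with follicle cells, 8.02 and 7.29 µm without mock strip 1 or 2, and 7.14 and 8.12 µm without SspA+HDM strip 1 or 2. The causes were not tested. The ratios of Uox and Hsd11b2 rest on 25 mock transcripts each, fewer than the highest control feature of that section (34). No paired analysis was possible because there was 1 sample per treatment.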

Other observations

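The split of each strip at its midpoint and the comparison of Cd8a among cells with Cd3d were tests chosen after the data were seen. The SspA+HDM skin was deeper on its right than on its left in both strips. The labels leave open whether the strips are from 1 specimen, and if they are, this is 1 observation and not a repeated one. The outer epithelial layer had medians of 70.1 and 75.1 µm on the left of strips 1 and 2 and 102 and 104 µm on the right. In mock the values were 42.7 and 39.6 µm on the left and 39.6 and 40.3 µm on the right. Within keratinocyte-like cells, Uox was at 3935 and 3900 CPM on the left and 10343 and 10439 on the right, and Areg at 1355 and 1404 on the left and 2738 and 2815 on the right. Cxcr2 ran the other way, at 2103 and 2095 CPM on the left and 1396 and 1357 on the right. Krt16 was at 66650 and 65747 on the left and 66590 and 69067 on the right. Macrophage-or-monocyte-like cells were at 168 and 200 per mm of strip on the left and 214 and 222 on the right, and cluster 12 follicle cells at 97.4 and 119 on the left and 148 and 183 on the right. No explanation was tested.

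Keratinocyte-like outlines with Cd3d differed in Cd8a between the sections. In mock, 112 such cells held Cd3d and 0 of them held Cd8a, which allows a share of up to 3.24% by the exact interval (2.68% at the floor of 3 counts). In SspA+HDM, 99 of 524 did, or 18.9% (15.6 to 22.5). The mock cells with Cd3d also held Rac2 6.31 times as often as their totals predict (4.23 to 9.06). The median total per keratinocyte-like cell was 164 in mock and 241 in SspA+HDM, and these shares were not thinned to 1 depth. Other classes were not compared in this way, and the direction of Cd8a CPM varied among them. It was 519 in mock and 462 in SspA+HDM in macrophage-or-monocyte-like cells, and 9.71 and 46.5 in adipocyte-like cells.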
